A study of Mus musculus with 12 samples.

How the data were processed

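Bulk RNA sequencing of whole lung from 12 C57BL6/J mice was analysed. The labels place 4 mice in each of 3 groups: a 0-week control, and mice given L-NAME together with a high-fat diet for 2 or 5 weeks. L-NAME is an inhibitor of nitric oxide synthase and was given at 0.5 g/L in the drinking water, and the diet held 60% lipid. Each library is a separate mouse. The labels carry mouse numbers, and libraries were numbered 1 to 4 within each group, so a replicate number only names a library and pairs nothing. A single-cell experiment that the series also describes was not analysed here.

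The authors deposited a single table of CPM values, with an offset of 0.0001 in every cell, so that libraries sum to between 1000002.3 and 1000002.4. TopHat2, Partek and the genome build mm10 are named, per the submitters' processing notes. Versions, gene annotation, strandedness and filters are not given in the sources used here. The table lists 23127 genes with Ensembl identifiers and symbols, of which 16698 are protein-coding and 2811 are lncRNA. A gene without reads appears at 0.0001 CPM, and 18400 genes lay above 0.001 CPM in all 12 libraries. The 38 repeated symbols were told apart by identifier. Of 23058 nuclear genes matched by identifier to GENCODE M21 on GRCm38, only 486 had the same start. Positions are therefore printed as the deposited table gives them, in a build that it does not name. The stop minus the start equalled the GENCODE gene length for 22662 of 23073 matched genes, so ends are printed as the stop minus 1.

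The depth was read from the low CPM values, which lie mostly on multiples of one step per library. That step corresponds to between 26000000 and 34100000 reads assigned to genes per library. Between 87.7% and 88.3% of the values from 1 to 20 steps lay within 0.1 of a whole step, too few for whole reads to be recovered, and no count model was fitted. The 10 most abundant genes took between 7.47% and 9.89% of the CPM in each library. Without recovered counts, no interval for counting error is given. No pair of the 12 libraries was identical, and Pearson's r across genes lay between 0.9524 and 0.9946 over the 66 pairs.

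Values were analysed as log2(CPM + 1) for the 15562 genes with a mean of at least 1 CPM over the 12 libraries. Fold changes are on this scale, which understates the change of genes of low expression. Limma 3.58.1 in R 4.3.3 fitted a mean per group over all 12 libraries and moderated the variances with a trend on expression. Two-sided tests compared 2 weeks with 0 weeks, 5 weeks with 0 weeks and 5 weeks with 2 weeks, and a moderated F-test covered all 3 groups. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 47 lists of cell type markers, tissue markers and pathway genes, the tests and the rule for named genes were fixed before the data were examined. The 44 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation, fry, camera on ranks and an exact two-sided permutation test of the list mean per library stand beside it. With 4 against 4 mice the smallest p of that permutation test is 0.0286. Members of a list are also counted with p-values adjusted over the list alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the depth check, the tallies of alternatives and plots.

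The gene and list tests were tested on simulated counts drawn from the real means, spreads and depths, for the comparison of 5 with 0 weeks. Over 5 runs, the first of which tested 15470 genes, limma recovered 49.4% of genes changed 1.5-fold. It recovered 82% of those changed 2-fold and 94.7% of those changed 4-fold, with 35 false calls in all. The simulated genes varied independently of each other, unlike genes of a tissue that shift together. In 20 runs, camera called a list shifted 1.5-fold in all 20 and called an unshifted list 2 times.

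The rule names Il1b always, and the extreme fold changes among genes past the threshold or, where none passed, the 5 with the smallest p. From each list that passed without a passing member it names the 2 members with the smallest p. Predicted genes are counted and not named. Among the genes that the rule names, 1 is not reported here. Genes outside the rule are named as chosen after their values were seen. The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of 10 CPM, median-of-ratios and quantile scaling, library weights and robust variance moderation. A minimum absolute log2 change of 1, fits of only the groups compared, other list tests, and leaving out each library in turn were tried as well. Genes with near-identical copies, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or Hspa1a and Hspa1b, are uncertain individually, because the counting is not stated to separate them. Overlapping and antisense genes are likewise uncertain.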

Results

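Whole-lung RNA was profiled in 12 mice after 0, 2 or 5 weeks of combined L-NAME and high-fat diet. The series concerns IL-1β from myeloid cells in the pulmonary vascular remodelling of heart failure with preserved ejection fraction. The 3 groups held 4 mice each: 0-week controls, and mice treated for 2 or 5 weeks. Between 26000000 and 34100000 reads per library were assigned to genes, as read from the steps of the low values. The only untreated group was that of 0 weeks, so time on study and treatment changed together. Control replicate 2, 2-week replicate 3 and 5-week replicate 3 stood apart on the main principal components, and list means without these 3 libraries were examined after the data were seen.

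Il1b, which encodes the inflammatory cytokine IL-1β (ENSMUSG00000027398, chromosome 2, 129206490 to 129213059 as the deposited table places it), averaged 11.8 ± 4.28 CPM in the 0-week controls (SD, n = 4). It averaged 9.64 ± 6.04 CPM after 2 weeks and 28.2 ± 11.7 CPM after 5 weeks (SD, n = 4). The 5-week mean was 2.39 times the control mean and 2.93 times the 2-week mean, with overlapping libraries. Exact two-sided permutation tests on log2(CPM + 1) gave p = 0.486 for 2 against 0 weeks. For 5 against 0 weeks and for 5 against 2 weeks the exact permutation p was 0.0571. None of the 3 differences passed in limma (adjusted p = 0.754, 0.521 and 0.288). Without 2-week replicate 4 the adjusted p for 5 against 2 weeks was 0.0208, and with library weights it was 0.0229. Over its 22 alternatives it lay between 0.0208 and 0.665.

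**Figure D1:**
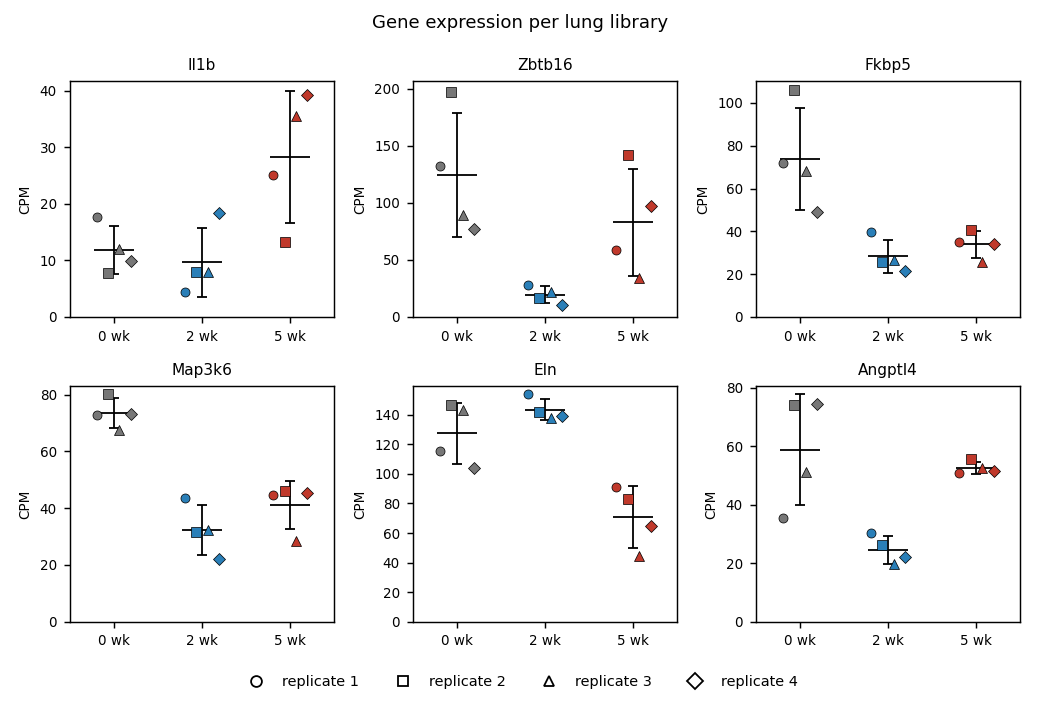
CPM of 6 genes in each lung library (y axis, linear, from 0) by weeks of L-NAME and high-fat diet (x axis), where marker shapes give the replicate and bars the group mean and SD (n = 4). Il1b averaged 28.2 CPM at 5 weeks against 11.8 CPM in controls with overlapping libraries, and Zbtb16, Fkbp5 and Map3k6 lay lower in all 4 libraries at 2 weeks than in any control.

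The comparison of 2 with 0 weeks addresses the early response of the lung. As a list, glucocorticoid response genes fell. Their list mean was 6.32 ± 0.16 against 6.68 ± 0.07 (mean log2(CPM + 1), SD, n = 4), with 11 of 16 members lower and every treated library below every control (camera adjusted p = 8.84e-05, adjusted p = 0.703 with an estimated correlation). The exact permutation p of the list mean was 0.0286, the smallest that 4 against 4 libraries allow (adjusted 0.627). Zbtb16, a transcriptional repressor (ENSMUSG00000066687, chromosome 9, 48565597 to 48747522), averaged 19.4 ± 7.56 CPM against 124 ± 54.4 CPM (SD, n = 4). Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28618068 to 28736501), averaged 28.3 ± 7.84 CPM against 73.8 ± 23.7 CPM. Both passed adjusted over the list alone, as the only 2 members, and neither passed over all genes (adjusted p = 0.0835 for each). Aryl hydrocarbon receptor targets, which did not pass with camera, were the only other list at that smallest permutation p at 2 weeks. They stood at 5.243 to 5.488 in the 2-week libraries, against 4.874 to 5.199 in the controls.

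Immediate early genes rose as a list, with 16 of 19 members higher and 10 past the threshold adjusted over the list alone (camera adjusted p = 4.93e-06, adjusted p = 0.747 with an estimated correlation). The AP-1 subunit gene Fosb had a log2 difference of 1.16 ± 0.22 (SE), whereas the nuclear receptor gene Nr4a3 had -1.95 ± 0.35. The list mean of 0.43 was 0.29 without 2-week replicate 2. Cholesterol synthesis genes rose by a mean log2 difference of 0.23, with 19 of 20 members higher (camera adjusted p = 1.2e-07, adjusted p = 0.747 with an estimated correlation). Of these, 7 passed adjusted over the list alone, among them Idi1 (0.46 ± 0.10) and Fdps (0.40 ± 0.09), enzymes of the isoprenoid steps. Heat shock genes fell, with 17 of 18 members lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 2.52e-05, adjusted p = 0.756 with an estimated correlation). The chaperone genes Hspa8 and Dnaja1 had log2 differences of -0.59 ± 0.19 and -0.52 ± 0.18. The heat shock mean of -0.31 was -0.15 without control replicate 4.

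Macrophage and antigen presentation markers were lower at 2 weeks. Interstitial macrophage markers fell by 0.42 (mean log2 difference), with 15 of 16 members lower and 3 past the threshold adjusted over the list alone (camera adjusted p = 1.2e-07, adjusted p = 0.747 with an estimated correlation). The haemoglobin scavenger receptor gene Cd163 averaged 11.3 ± 0.771 CPM against 22.03 ± 10.3 CPM, and the apolipoprotein gene Apoe 648 ± 26.4 CPM against 909 ± 197 CPM (SD, n = 4). Alveolar macrophage markers fell by 0.46, with 15 of 17 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 2.52e-05, adjusted p = 0.747 with an estimated correlation). Among them the proton pump subunit gene Atp6v0d2 stood at -0.72 ± 0.29 and the keratin gene Krt19 at 0.28 ± 0.11 (log2, SE). Dendritic cell and MHC class II genes fell by 0.21, with 2 past the threshold adjusted over the list alone (camera adjusted p = 6.03e-05, adjusted p = 0.747 with an estimated correlation). These were the chemokine genes Ccl22 (-0.61 ± 0.15) and Ccl17 (-0.54 ± 0.15). The mean was -0.26 without control replicate 2 and -0.23 without the 3 libraries that stand apart for interstitial macrophage markers, -0.70 without control replicate 3, -0.69 without 2-week replicate 4 and -0.23 without the 3 libraries that stand apart for alveolar macrophage markers and -0.12 without 2-week replicate 1 and -0.31 without 2-week replicate 4 for dendritic cell genes. In 2-week replicate 4 alveolar macrophage markers stood at 5.16, against 4.09 to 4.35 in the other 2-week libraries. Control replicate 3 stood at 4.21, against 5.12 to 5.22 in the other controls.

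The IL-1 family and inflammasome list fell by 0.16 at 2 weeks, with 18 of 21 members lower (camera adjusted p = 0.000868, adjusted p = 0.747 with an estimated correlation). The alarmin gene Il33 (-0.49 ± 0.12, log2, SE) was the only 1 member past the threshold adjusted over the list alone. Il1rl1, which encodes the receptor of IL-33, stood at -0.46 ± 0.14. The list mean was -0.27 without 2-week replicate 4. Monocyte markers fell by 0.14 (camera adjusted p = 0.0448, adjusted p = 0.899 with an estimated correlation), with Cd300ld at -0.74 ± 0.25 and Csf1r at -0.24 ± 0.12. The monocyte mean was -0.06 (not passing) without control replicate 1, -0.05 (not passing) without control replicate 2, -0.29 without control replicate 3, -0.03 (not passing) without 2-week replicate 1, -0.12 (not passing) without 2-week replicate 2, -0.11 (not passing) without 2-week replicate 3, -0.32 without 2-week replicate 4, -0.14 (not passing) without 5-week replicate 3, -0.14 (not passing) without 5-week replicate 4 and -0.02 (not passing) without the 3 libraries that stand apart, and the list did not pass with median-of-ratios scaling (adjusted p = 0.0747). Cell cycle genes fell by 0.12 (camera adjusted p = 0.0272, adjusted p = 0.899 with an estimated correlation), with the mitotic kinase genes Aurkb at -0.45 ± 0.17 and Cdk1 at -0.35 ± 0.20. Their mean was -0.10 (not passing) without control replicate 1, -0.01 (not passing) without control replicate 2, -0.19 without control replicate 4, -0.05 (not passing) without 2-week replicate 2 and -0.001 (not passing) without the 3 libraries that stand apart, and they did not pass with median-of-ratios scaling (adjusted p = 0.0511). Of monocyte and cell cycle genes 0 and 0 passed adjusted over the list alone.

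Smooth muscle contractile genes rose by 0.21 at 2 weeks, with 12 of 16 members higher and 7 past the threshold adjusted over the list alone (camera adjusted p = 0.00409, adjusted p = 0.747 with an estimated correlation). Acta2, which encodes smooth muscle actin (chromosome 19, 34218490 to 34232990), averaged 354 ± 33.7 CPM against 262 ± 24.8 CPM (SD, n = 4). Tagln, which encodes transgelin, averaged 284 ± 24.1 CPM against 219 ± 24.5 CPM. In 2-week replicate 4 the list stood at 6.14, against 6.45 to 6.46 in the other 2-week libraries. Ciliated cell markers rose by 0.22, with 16 of 16 members higher and 1 past the threshold adjusted over the list alone (camera adjusted p = 0.00324, adjusted p = 0.824 with an estimated correlation). Ccdc39 stood at 0.44 ± 0.12 and Ccdc113 at 0.42 ± 0.16 (log2, SE), and the list mean was 0.34 without 2-week replicate 4 and 0.14 (not passing) without the 3 libraries that stand apart. Nuclear-encoded oxidative phosphorylation genes rose by 0.12, with 0 past the threshold adjusted over the list alone (camera adjusted p = 0.0354, adjusted p = 0.899 with an estimated correlation). The complex I genes Ndufs1 and Ndufv1 stood at 0.23 ± 0.12 and 0.20 ± 0.11. This mean was 0.03 (not passing) without control replicate 4 and 0.06 (not passing) without 2-week replicate 3.

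Adipocyte genes fell by 0.69 at 2 weeks, and fatty acid synthesis genes fell by 0.39. For adipocyte genes the camera adjusted p was 0.00254, adjusted p = 0.864 with an estimated correlation. For fatty acid synthesis genes it was 0.0108, adjusted p = 0.842 with an estimated correlation. Neither list had a member past the threshold adjusted over the list alone. The lipid droplet gene Cidec stood at -1.11 ± 0.68, Pck1 at -1.52 ± 1.03, the desaturase genes Scd1 at -0.99 ± 0.41 and Fads1 at 0.17 ± 0.06 (log2, SE). In control replicate 2 adipocyte genes stood at 6.57, against 2.81 to 3.51 in the other controls. The adipocyte mean was 0.16 (not passing) without control replicate 2, -1.09 without control replicate 3, -0.49 (not passing) without 2-week replicate 4 and 0.25 (not passing) without the 3 libraries that stand apart. That of fatty acid synthesis was -0.04 (not passing) without control replicate 2, -0.38 (not passing) without 2-week replicate 4 and -0.05 (not passing) without the 3 libraries that stand apart.

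In limma 0 of 15562 genes passed at 2 weeks, where 1438 had an unadjusted p under 0.05 (890 higher, 548 lower) and chance gives 778. That count was 943 without control replicate 4, 945 without 2-week replicate 3 and 2275 without 2-week replicate 4. Library weights passed 18 genes. Without 5-week replicate 3, 24 genes passed, and without control replicate 1 only Angptl4 did, named after its values were seen. Treated libraries lay on one side of all controls for 828 genes, 5.32% where chance gives 2.86% on average over groupings. The named genes with the smallest p were of this kind, at an adjusted p of 0.0835. Map3k6, a stress-activated kinase (chromosome 4, 132968129 to 132980240), averaged 32.4 ± 8.86 CPM against 73.5 ± 5.19 CPM (SD, n = 4). Itgb6, an epithelial integrin subunit, averaged 32.9 ± 2.57 CPM against 20.6 ± 2.69 CPM. The anion exchanger gene Slc26a4 stood at -0.85 ± 0.14 and the transcription factor gene Klf10 at -0.72 ± 0.12 (log2, SE). Of the 44 lists 15 passed with camera, 5 higher and 10 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.703), and 0 passed with fry (lowest 0.227).

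The comparison of 5 with 0 weeks addresses the longer treatment. Lists of NK cell, B cell, neutrophil, monocyte and T cell markers rose. NK cell and cytotoxic genes had a mean of 2.88 ± 0.15 against 2.23 ± 0.27 (mean log2(CPM + 1), SD, n = 4), with 15 of 15 members higher and every treated library above every control (camera adjusted p = 1.32e-12, adjusted p = 0.478 with an estimated correlation). The granule gene Nkg7 averaged 11.9 ± 1.32 CPM against 6.17 ± 1.77 CPM, and the receptor gene Klra8 3.77 ± 1.16 CPM against 1.73 ± 0.291 CPM (SD, n = 4). B cell markers rose by a mean log2 difference of 0.73, with 16 of 16 higher (camera adjusted p = 4.33e-10, adjusted p = 0.519 with an estimated correlation). The receptor gene Fcer2a stood at 1.01 ± 0.27 (log2, SE). Neutrophil markers rose by 0.89, with 12 of 12 higher (camera adjusted p = 3.18e-08, adjusted p = 0.519 with an estimated correlation), among them Cd177 (0.80 ± 0.15) and Retnlg (1.40 ± 0.41). Monocyte markers rose by 0.52, with 16 of 17 higher (camera adjusted p = 7.56e-07, adjusted p = 0.525 with an estimated correlation). Treml4 averaged 8.30 ± 1.45 CPM against 4.13 ± 1.11 CPM and the Fc receptor gene Fcgr4 9.82 ± 1.25 CPM against 5.26 ± 1.31 CPM. T cell markers rose by 0.28 (camera adjusted p = 0.0005, adjusted p = 0.632 with an estimated correlation), with Lck at 0.56 ± 0.21 and Trac at 0.45 ± 0.20, and their mean was 0.16 (not passing) without control replicate 3 and 0.18 (not passing) without the 3 libraries that stand apart. Adjusted over the list alone, 12 NK cell, 13 B cell, 10 neutrophil, 7 monocyte and 0 T cell genes passed. The B cell, neutrophil, monocyte and T cell lists overlapped between the groups. B cell markers stood at 4.635 in control replicate 2, against 4.555 to 4.613 in 5-week replicates 1, 2 and 4 and 5.389 in 5-week replicate 3. Neutrophil markers stood at 3.512 in control replicate 1, against 3.155 in 5-week replicate 2. Alveolar macrophage markers (0.20, camera adjusted p = 0.145) and dendritic cell and MHC class II genes (0.14, camera adjusted p = 0.0906) did not pass.

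Red cell transcripts were higher on average at 5 weeks, though not in 5-week replicate 2, whose list mean lay within the range of the controls. Red cell and haemoglobin genes rose by 1.31, with 7 of 7 members higher and 7 past the threshold adjusted over the list alone (camera adjusted p = 5.99e-06, adjusted p = 0.519 with an estimated correlation). Alas2, the haem synthesis enzyme of red cell precursors, averaged 40.8 ± 33.8 CPM against 11.6 ± 4.85 CPM, and Bpgm 50.6 ± 19.2 CPM against 32.7 ± 4.57 CPM (SD, n = 4). In 5-week replicate 3 the list stood at 9.13, against 6.26 to 7.501 in the other 5-week libraries, and its mean was 0.79 without 5-week replicate 3 and 0.68 without the 3 libraries that stand apart. Ribosomal protein genes rose by 0.15, with Rps16 at 0.38 ± 0.14 and Rps3 at 0.30 ± 0.17 (log2, SE), and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00851, adjusted p = 0.75 with an estimated correlation). Their mean was 0.06 (not passing) without control replicate 4, -0.01 (not passing) without 5-week replicate 3 and -0.003 (not passing) without the 3 libraries that stand apart. The IL-1 family and inflammasome list rose by 0.22, with 15 of 21 members higher and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.0384, adjusted p = 0.686 with an estimated correlation). Gsdmd, which encodes a pore-forming protein, stood at 0.38 ± 0.11. Il1rn, which encodes the IL-1 receptor antagonist, averaged 13.1 ± 2.61 CPM against 7.58 ± 1.82 CPM. The IL-1 family mean was 0.15 (not passing) without control replicate 3, 0.18 (not passing) without 5-week replicate 3, 0.19 (not passing) without 5-week replicate 4 and 0.20 (not passing) without the 3 libraries that stand apart, and the list did not pass with camera on ranks (adjusted p = 0.0607).

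**Figure D2:**
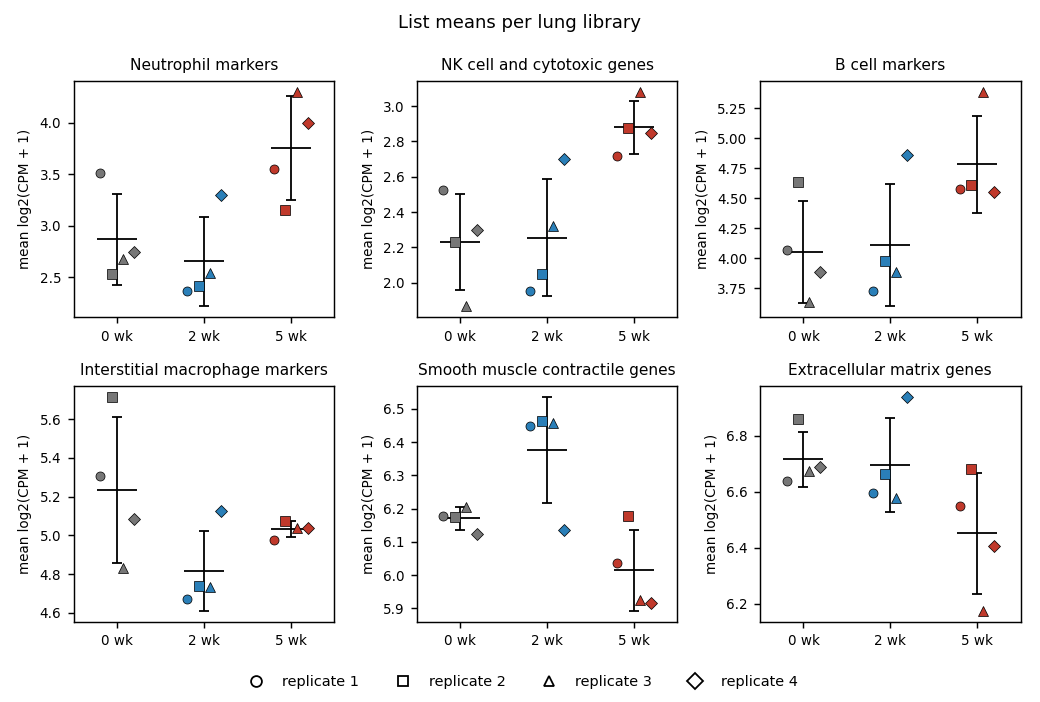
Mean log2(CPM + 1) of 6 gene lists in each lung library (y axis) by weeks of treatment (x axis), where marker shapes give the replicate and bars the group mean and SD (n = 4). NK cell genes averaged 2.88 at 5 weeks against 2.23 in controls, and smooth muscle genes 6.01 at 5 weeks against 6.38 at 2 weeks, with 2-week replicate 4 at 6.14.

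Matrix, contractile and secretory genes were lower at 5 weeks. Extracellular matrix and remodelling genes fell by 0.26, with 21 of 25 members lower (camera adjusted p = 3.18e-08, adjusted p = 0.519 with an estimated correlation). Eln, which encodes elastin (ENSMUSG00000029675, chromosome 5, 134731447 to 134776177), averaged 70.9 ± 20.7 CPM against 127 ± 20.8 CPM (SD, n = 4). Lox, which crosslinks elastin and collagen, averaged 47.4 ± 2.41 CPM against 72.8 ± 11.9 CPM. These were the 2 members past the threshold adjusted over the list alone, and the list mean was -0.17 without 5-week replicate 3 and -0.12 without the 3 libraries that stand apart. Smooth muscle contractile genes fell by 0.16, with 14 of 16 lower (camera adjusted p = 0.000707, adjusted p = 0.519 with an estimated correlation). The coactivator gene Myocd (-0.60 ± 0.15, log2, SE) was the only 1 past the threshold adjusted over the list alone, beside Smtn at -0.29 ± 0.11. Club and secretory cell markers fell by 0.62, with 14 of 15 lower and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.525 with an estimated correlation). The mucin gene Muc5b averaged 29.1 ± 13.6 CPM against 58.7 ± 7.28 CPM and Gabrp stood at -0.17 ± 0.09. The club cell mean was -0.39 without 5-week replicate 1, -0.41 without 5-week replicate 4 and -0.90 without the 3 libraries that stand apart. 5-week replicates 1 and 4 stood at 5.329 and 5.403 and replicate 2 at 6.432, against 6.448 to 6.817 in the controls. 5-week replicate 3 stood at 6.93, above every control. Cardiac muscle genes fell by 0.27, with 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00602, adjusted p = 0.727 with an estimated correlation), and Actc1 at -0.37 ± 0.20 and Pln at -0.54 ± 0.39. This mean was -0.11 (not passing) without control replicate 2, -0.47 without control replicate 4, -0.45 without 5-week replicate 3 and -0.11 (not passing) without 5-week replicate 4.

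Lists of vascular signalling fell by small amounts at 5 weeks. Nitric oxide, endothelin and vascular tone genes fell by 0.06, with 15 of 25 lower (camera adjusted p = 0.0408, adjusted p = 0.57 with an estimated correlation). The endothelial nitric oxide synthase gene Nos3 stood at -0.36 ± 0.15 and the endothelin receptor gene Ednra at -0.19 ± 0.10 (log2, SE). Nos3 was lowest in 5-week replicate 3, at 19.36 CPM against 25.87 to 32.46 CPM in the other 5-week libraries. BMP signalling and pulmonary hypertension genes fell by 0.08, with 19 of 25 lower (camera adjusted p = 0.0184, adjusted p = 0.632 with an estimated correlation). The transcription factor genes Sox17 and Klf4 stood at -0.27 ± 0.14 and -0.54 ± 0.29. Single libraries weigh on both. Sox17 was at 137.4 CPM in control replicate 3, against 76.06 to 106.06 CPM in the other controls. Klf4 was at 157.6 CPM in 5-week replicate 3, against 290.03 to 354.97 CPM in the other 5-week libraries. In either list 0 members passed adjusted over the list alone. The vascular tone mean was -0.06 (not passing) without control replicate 3, -0.03 (not passing) without control replicate 4, -0.07 (not passing) without 5-week replicate 2, -0.03 (not passing) without 5-week replicate 3, -0.06 (not passing) without 5-week replicate 4 and -0.04 without the 3 libraries that stand apart. The BMP mean was -0.05 (not passing) without control replicate 3, -0.05 (not passing) without control replicate 4, -0.03 (not passing) without 5-week replicate 3 and -0.05 without the 3 libraries that stand apart.

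Glucocorticoid response genes fell by 0.23 at 5 weeks, with 10 of 16 members lower and 4 past the threshold adjusted over the list alone (camera adjusted p = 0.000174, adjusted p = 0.478 with an estimated correlation). Among these were the metallothionein gene Mt2 (-0.84 ± 0.15, log2, SE) and Fkbp5 (-1.07 ± 0.22). Immediate early genes rose by 0.34, with 17 of 19 higher and 10 past the threshold adjusted over the list alone (camera adjusted p = 5.95e-05, adjusted p = 0.57 with an estimated correlation). Fosb stood at 0.89 ± 0.22 and Nr4a3 at -1.77 ± 0.35. Cholesterol synthesis genes rose by 0.16, with 20 of 20 higher and 3 past the threshold adjusted over the list alone (camera adjusted p = 0.000174, adjusted p = 0.542 with an estimated correlation), with Idi1 at 0.39 ± 0.10 and Fdps at 0.34 ± 0.09. The glucocorticoid mean was -0.15 without the 3 libraries that stand apart and the cholesterol synthesis mean 0.26 without the 3 libraries that stand apart. Interstitial macrophage markers fell by 0.20, with 12 of 16 lower (camera adjusted p = 0.000278, adjusted p = 0.542 with an estimated correlation). Lyve1 averaged 238 ± 49.6 CPM against 372 ± 88.3 CPM (SD, n = 4), Cd163 stood at -0.75 ± 0.24, and the list mean was -0.04 without control replicate 2, -0.34 without control replicate 3 and -0.05 without the 3 libraries that stand apart. Heat shock genes fell by 0.18 (camera adjusted p = 0.00182, adjusted p = 0.632 with an estimated correlation), with Bag3 at -0.27 ± 0.12 and Hspd1 at -0.12 ± 0.08. The heat shock mean was -0.33 without control replicate 1, -0.12 (not passing) without control replicate 3, -0.02 (not passing) without control replicate 4 and -0.12 without 5-week replicate 3. Of interstitial macrophage and heat shock genes 0 and 0 passed adjusted over the list alone.

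Adipocyte genes fell by 0.75 at 5 weeks, with the adipokine genes Cfd at -1.72 ± 0.99 and Retn at -1.33 ± 0.81 (log2, SE; camera adjusted p = 0.000595, adjusted p = 0.632 with an estimated correlation). Their mean was 0.10 (not passing) without control replicate 2, -1.15 without control replicate 3 and -0.19 without the 3 libraries that stand apart. Fatty acid synthesis genes fell by 0.49, with Scd1 at -0.99 ± 0.41 and Thrsp at -1.77 ± 0.77 (camera adjusted p = 2.85e-05, adjusted p = 0.525 with an estimated correlation), and their mean was -0.14 without control replicate 2 and -0.11 (not passing) without the 3 libraries that stand apart. Control replicate 2 stood at 6.57 for adipocyte and 8.04 for fatty acid synthesis genes, the highest of the controls in both. Mitochondrially encoded genes fell by 0.22, with 13 of 13 lower (camera adjusted p = 1.56e-05, adjusted p = 0.525 with an estimated correlation). The complex I genes mt-Nd5 and mt-Nd4 stood at -0.36 ± 0.17 and -0.30 ± 0.15. Circadian clock genes fell by 0.12, with 14 of 17 lower (camera adjusted p = 0.00151, adjusted p = 0.525 with an estimated correlation), Bhlhe40 at -0.20 ± 0.08 and Cry2 at -0.21 ± 0.10. The clock mean was -0.05 without 5-week replicate 3 and -0.07 without the 3 libraries that stand apart. None of these 4 lists had a member past the threshold adjusted over the list alone.

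In limma 0 of 15562 genes passed at 5 weeks, where 1343 had an unadjusted p under 0.05 (909 higher, 434 lower) and chance gives 778. Library weights also passed 0, and only Hes2 passed without control replicate 1. Groups did not overlap for 779 genes, 5.01% where chance gives 2.86% on average over groupings. The named genes with the smallest p were among these. Hes2, of the Hes family of repressors (chromosome 4, 152243324 to 152246926), averaged 6.10 ± 0.819 CPM against 2.71 ± 0.684 CPM (SD, n = 4; adjusted p = 0.191). Bex2 stood at 0.82 ± 0.14, Acoxl at 0.58 ± 0.10, the amino acid transporter gene Slc6a20a at 0.60 ± 0.10 and Slc26a4 at -0.76 ± 0.14 (log2, SE), each with an adjusted p of 0.215. Of the 44 lists 23 passed with camera, 10 higher and 13 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.478), and 0 passed with fry (lowest 0.247).

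The comparison of 5 with 2 weeks tests the difference between the treated groups itself. Lists of neutrophil, monocyte, NK, B and T cell markers rose. Neutrophil markers rose by a mean log2 difference of 1.10, with 11 of 12 members higher (camera adjusted p = 2.53e-10, adjusted p = 0.281 with an estimated correlation). The chemokine receptor gene Cxcr2 averaged 20.3 ± 8.38 CPM against 6.09 ± 3.82 CPM, and the protease gene Mmp9 31.2 ± 10.8 CPM against 10.5 ± 6.64 CPM (SD, n = 4). Monocyte markers rose by 0.67 (camera adjusted p = 1.18e-10, adjusted p = 0.281 with an estimated correlation), with Fcgr4 at 1.19 ± 0.23 and Cd300ld at 1.43 ± 0.25 (log2, SE). NK cell genes rose by 0.62 (camera adjusted p = 1.26e-11, adjusted p = 0.281 with an estimated correlation), with Nkg7 at 0.85 ± 0.19 and the chemokine gene Ccl5 at 0.82 ± 0.19. B cell markers rose by 0.67 (camera adjusted p = 4.02e-09, adjusted p = 0.34 with an estimated correlation), with Cd22 at 0.81 ± 0.26 and Cd79a at 0.77 ± 0.28, and their mean was 0.40 without the 3 libraries that stand apart. In 5-week replicate 3 Cd79a stood at 121 CPM, against 51.3 to 59.1 CPM in the other 5-week libraries. The B cell list of 2-week replicate 4 stood at 4.862, within the 5-week range of 4.555 to 5.389. That library also lay within the 5-week range for neutrophil markers (3.295, range 3.155 to 4.3) and monocyte markers (4.979, range 4.881 to 5.322). The same held for T cell markers (2.841, range 2.629 to 3.022) but not for NK cell genes (2.699, range 2.719 to 3.081). T cell markers rose by 0.38 (camera adjusted p = 1.18e-07, adjusted p = 0.423 with an estimated correlation), with Cd3g at 0.58 ± 0.19 and Il7r at 0.46 ± 0.16, and their mean was 0.25 without the 3 libraries that stand apart. Red cell genes rose by 1.26 (camera adjusted p = 1e-05, adjusted p = 0.34 with an estimated correlation), with Hbb-bs at 1.61 ± 0.57 and Hbb-bt at 1.56 ± 0.55, and their mean was 0.74 without 5-week replicate 3 and 0.60 without the 3 libraries that stand apart. Adjusted over the list alone, 11 neutrophil, 11 monocyte, 11 NK cell, 7 B cell, 0 T cell and 6 red cell genes passed.

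The IL-1 family, dendritic cell and alveolar macrophage lists rose between 2 and 5 weeks. The IL-1 family and inflammasome list rose by 0.38, with 20 of 21 members higher (camera adjusted p = 4.5e-08, adjusted p = 0.281 with an estimated correlation). The members with the smallest p were Il1rn at 1.17 ± 0.24 and Il1b at 1.51 ± 0.39 (log2, SE). Dendritic cell and MHC class II genes rose by 0.34 (camera adjusted p = 2.87e-08, adjusted p = 0.281 with an estimated correlation), with H2-DMb1 at 0.59 ± 0.13 and H2-Aa at 0.51 ± 0.12. Alveolar macrophage markers rose by 0.65 (camera adjusted p = 4.33e-08, adjusted p = 0.34 with an estimated correlation), with the ribonuclease genes Ear2 at 1.21 ± 0.29 and Ear1 at 1.04 ± 0.30. Adjusted over the list alone, 6 IL-1 family, 8 dendritic cell and 7 alveolar macrophage genes passed. In 2-week replicate 4 each of these lists lay within the 5-week range. That library stood at 3.661 for the IL-1 family (5-week range 3.571 to 3.816) and 5.168 for dendritic cells (5.091 to 5.371). For alveolar macrophages it stood at 5.16 (5.018 to 5.242). Interstitial macrophage markers (0.21, camera adjusted p = 0.0849) and mast cell, basophil and eosinophil markers (0.19, camera adjusted p = 0.762) did not pass. Red cell genes were higher in the same comparison, by 1.26.

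Smooth muscle contractile genes averaged 6.01 ± 0.12 against 6.38 ± 0.16 (mean log2(CPM + 1), SD, n = 4) and fell, with 15 of 16 members lower (camera adjusted p = 3.39e-09, adjusted p = 0.281 with an estimated correlation). The list also passed with fry (adjusted p = 0.0318), and 11 members passed adjusted over the list alone. Acta2 averaged 244 ± 22 CPM against 354 ± 33.7 CPM and the calponin gene Cnn1 66.9 ± 10.1 CPM against 107 ± 23.1 CPM. Extracellular matrix genes fell by 0.24 (camera adjusted p = 9.15e-05, adjusted p = 0.508 with an estimated correlation), with Eln at -1.05 ± 0.18 and Col1a1 at -0.60 ± 0.18 (log2, SE). Their mean was -0.16 without 2-week replicate 4 and -0.15 without 5-week replicate 3. Endothelial markers fell by 0.13 (camera adjusted p = 0.00161, adjusted p = 0.65 with an estimated correlation), with Plvap at -0.36 ± 0.10 and Erg at -0.22 ± 0.10, and their mean was -0.08 without 5-week replicate 3. Club and secretory cell markers fell by 0.67 (camera adjusted p = 1.01e-06, adjusted p = 0.34 with an estimated correlation), with Gabrp at -0.33 ± 0.09 and Hp at -0.37 ± 0.13. The club cell mean was -0.36 without 2-week replicate 1, -0.44 without 5-week replicate 1 and -1.08 without the 3 libraries that stand apart. 5-week replicate 3 stood at 6.93, within the 2-week range of 5.857 to 7.647. Ciliated cell markers fell by 0.21 (camera adjusted p = 0.000848, adjusted p = 0.526 with an estimated correlation), with Ccdc39 at -0.44 ± 0.12 and Foxj1 at -0.30 ± 0.13, and their mean was -0.33 without 2-week replicate 4. Adjusted over the list alone, 1 matrix, 1 club cell, 1 ciliated cell and 0 endothelial genes passed.

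Cardiac muscle genes fell by 0.50 between 2 and 5 weeks (camera adjusted p = 0.000188, adjusted p = 0.657 with an estimated correlation), with Actc1 at -0.62 ± 0.20 and Ttn at -1.54 ± 0.74 (log2, SE), the latter -0.71 without 2-week replicate 3. Their mean was -0.21 (not passing) without 2-week replicate 2 and -0.86 without 2-week replicate 4. Mitochondrially encoded genes fell by 0.32, with 13 of 13 lower (camera adjusted p = 1.26e-07, adjusted p = 0.34 with an estimated correlation), mt-Nd2 at -0.40 ± 0.13 and mt-Nd4l at -0.48 ± 0.17. The mitochondrial mean ran from -0.45 to -0.23 with 1 library left out and was -0.21 without the 3 libraries that stand apart. In 2-week replicate 4 the list stood at 9.765, below every 5-week library (9.802 to 9.914). Cell cycle genes rose by 0.24 (camera adjusted p = 2.1e-05, adjusted p = 0.526 with an estimated correlation), with Cdk1 at 0.56 ± 0.20 and Ccna2 at 0.52 ± 0.24, and their mean was 0.15 without the 3 libraries that stand apart. Unfolded protein response genes rose by 0.08 (camera adjusted p = 0.00457, adjusted p = 0.281 with an estimated correlation), with Ddit3 at 0.27 ± 0.11 and Xbp1 at 0.13 ± 0.06, and passed with fry (adjusted p = 0.0318). Ribosomal protein genes rose by 0.18 (camera adjusted p = 0.000188, adjusted p = 0.748 with an estimated correlation), with Rpl32 at 0.37 ± 0.18 and Rps16 at 0.28 ± 0.14, and their mean was 0.01 (not passing) without 5-week replicate 3 and 0.004 (not passing) without the 3 libraries that stand apart. Cholesterol synthesis genes fell by 0.07 (camera adjusted p = 0.0435, adjusted p = 0.76 with an estimated correlation), with Mvk at -0.25 ± 0.11 and Fdft1 at -0.27 ± 0.13. The cholesterol synthesis mean was -0.04 (not passing) without 2-week replicate 4, -0.12 without 5-week replicate 1, -0.04 (not passing) without 5-week replicate 3 and -0.04 (not passing) without 5-week replicate 4. None of these lists had a member past the threshold adjusted over the list alone.

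Transcripts of other tissues stood out in 3 libraries. The summed CPM of 14 skeletal muscle genes was 12900 in 2-week replicate 3 and 590.5 in control replicate 2, against 20.35 to 69.4 in the other libraries. Skeletal muscle genes fell by 2.21 from 2 to 5 weeks (camera adjusted p = 0.000332, adjusted p = 0.657 with an estimated correlation), with Ckm at -2.05 ± 1.09 and Tnnt3 at -2.51 ± 1.38 (log2, SE). The mean was -0.18 (not passing) without 2-week replicate 3 and -0.22 without the 3 libraries that stand apart. Control replicate 2 held 3235 CPM of adipocyte genes, against 182.7 to 305.5 in the other controls. In 5-week replicate 3 red cell genes summed to 16230 CPM, against 1512 to 4494 in the other 5-week libraries. These are the 3 libraries that stand apart on the main principal components. Without them 14, 21 and 23 lists passed at 2 weeks, at 5 weeks and between these times, and limma passed 0 genes in each. Of the 59 list calls as reported 49 were kept without them, 8 were lost and 2 turned.

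**Figure D3:**
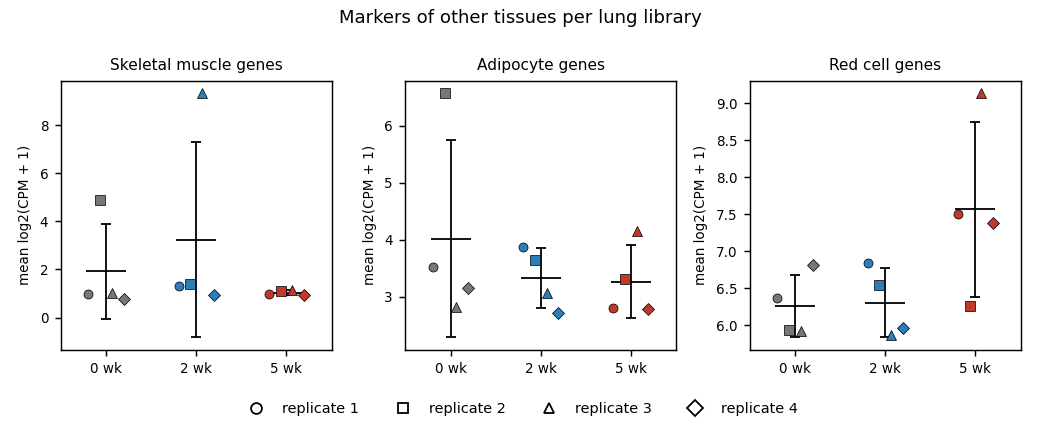
Mean log2(CPM + 1) of skeletal muscle, adipocyte and red cell lists in each lung library (y axis) by weeks of treatment (x axis), where marker shapes give the replicate and bars the group mean and SD (n = 4). Skeletal muscle genes stood at 9.32 in 2-week replicate 3, adipocyte genes at 6.57 in control replicate 2 and red cell genes at 9.13 in 5-week replicate 3.

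In limma 0 of 15562 genes passed between 2 and 5 weeks, where 1696 had an unadjusted p under 0.05 (961 higher, 735 lower) and chance gives 778. That count was 1130 without 2-week replicate 2, 1075 without 2-week replicate 3 and 2582 without 2-week replicate 4. Without 2-week replicate 4, 386 genes passed, and with library weights 881 did, 579 higher and 302 lower. Groups did not overlap for 769 genes, 4.94% where chance gives 2.86% on average over groupings. The named genes with the smallest p were Eln, Acta2, Cd300ld, Angptl4 and Gpr141, each without overlap and with an adjusted p of 0.276. Angptl4, an inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33992724 to 34000804), averaged 52.6 ± 2.02 CPM against 24.6 ± 4.73 CPM. The receptor gene Gpr141 averaged 7.59 ± 0.96 CPM against 3.59 ± 1.12 CPM (SD, n = 4). Of the 44 lists 21 passed with camera, 12 higher and 9 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.281). With fry 3 passed: smooth muscle, unfolded protein response and aryl hydrocarbon receptor targets, the last of which did not pass with camera (adjusted p = 0.0559).

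Over the 3 groups limma's moderated F-test passed 0 of 15562 genes, where 1681 had an unadjusted p under 0.05. It passed 286 genes with library weights, 134 without 2-week replicate 4, 5 without 5-week replicate 3 and 2 without control replicate 1. The 5 were Jade2, Thbs3, Zbtb16, Nr4a3 and Map3k6 and the 2 were Angptl4 and Hes2, where Jade2 and Thbs3 were named after their values were seen. The changes at 2 and 5 weeks share their 4 controls. Across genes, which are not independent replicates, both sets of log2 differences correlated with Pearson's r of 0.296 and had the same sign for 66.4% of genes. Unchanged groups that shared simulated controls, drawn as independent normal noise, gave a mean r of 0.50 and 66.6% over 100 runs. The covariance was 0.0130 against a simulated 0.0171, a difference of -0.00417. For each gene the simulated libraries all had the same spread, unlike the real ones. The lower observed values therefore cannot be read as less agreement than unchanged groups would give. The correlation was 0.454 without control replicate 3, 0.445 without 2-week replicate 3 and 0.123 without 2-week replicate 4. With the controls split into 2 and 2, the mean r over 6 assignments was -0.06, between -0.15 and 0.21. With 0 calls in limma at each time, 0 were shared.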

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

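The tests of a lower share of lung tissue cells and of a control label on 2-week replicate 4, the single-gene levels given for that library and control replicate 3, and the choice of the 3 libraries that stand apart on the main principal components (control replicate 2, 2-week replicate 3 and 5-week replicate 3), were made after the results were seen.

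Of 462 groups of 4 libraries examined, 42 had a library far from the other 3, where chance flags about 1 in 20 groups, or 23. In 2-week replicate 4 the list mean was 3.66 for the IL-1 family, 5.13 for interstitial macrophages and 2.84 for T cells, against at most 3.23, 4.74 and 2.26 in the other 2-week libraries. It was 4.92 for ciliated cells and 6.14 for smooth muscle, against at least 5.39 and 6.45. The same library stood apart for Atp6v0d2 at 33.3 CPM, Col1a1 at 511 CPM, Ear1 at 29.9 CPM, Ear2 at 86.2 CPM, Il1rn at 9.79 CPM and Il33 at 73.9 CPM. It also stood apart for Mmp9 at 20.5 CPM, mt-Nd4l at 68.3 CPM, Retnlg at 11 CPM, Rps3 at 519 CPM and Treml4 at 5.68 CPM. In 5-week replicate 3 B cell markers stood at 5.39, histone genes at 3.97 and ribosomal protein genes at 7.76. The genes that set it apart were Cd177 at 9.43 CPM, Cd22 at 36.1 CPM, Cd79a at 121 CPM, Cry2 at 68.4 CPM, Map3k6 at 28.5 CPM, mt-Nd4 at 2670 CPM, Ndufv1 at 84.8 CPM, Rpl32 at 450 CPM and Rps3 at 860 CPM. Skeletal muscle genes stood at 4.90 in control replicate 2 and 9.32 in 2-week replicate 3, with Tnnt3 at 34.8 and 677 CPM. Fatty acid oxidation genes stood at 6.14 in control replicate 2. Control replicate 3 stood apart with alveolar macrophage markers at 4.21 and Cd300ld at 5.25 CPM. The rest were mt-Nd4l at 67.6 CPM, Mt2 at 13.3 CPM and Mvk at 13.6 CPM in control replicate 4, Cidec at 5.6 CPM in 2-week replicate 3, Krt19 at 233 CPM in 2-week replicate 1, Myocd at 3.42 CPM in 2-week replicate 2 and Hspa8 at 1020 CPM in 5-week replicate 2.

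The treated groups differed from each other in 21 lists by camera, and in 0 with an estimated correlation. From 2 to 5 weeks the mean log2 difference was 0.38 for the IL-1 family, 1.10 for neutrophils, 0.67 for monocytes, 0.65 for alveolar macrophages, 0.34 for dendritic cells and 0.67 for B cells. It was 0.38 for T cells, 0.62 for NK cells, 1.26 for red cells, 0.08 for the unfolded protein response, 0.24 for the cell cycle and 0.18 for ribosomal proteins. Negative differences were -0.13 for endothelium, -0.67 for club cells, -0.21 for ciliated cells, -0.36 for smooth muscle and -0.24 for extracellular matrix. Those of cardiac muscle, skeletal muscle, cholesterol synthesis and mitochondrially encoded genes were -0.50, -2.21, -0.07 and -0.32.

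With 0 genes past the threshold in limma, every split of the 8 libraries gives as many by construction (35 of 35 in each comparison, and 100 of 100 drawn over the 3 groups), which says nothing about chance. The highest other count was 503 at 2 weeks, 0 at 5 weeks and between 2 and 5 weeks, and 615 over the 3 groups. Chance could not be excluded for the counts at an unadjusted p or of lists. The share of genes without overlap between groups was not computed for other splits, so its excess over chance was not tested. At an unadjusted p under 0.05, 3 of 35 splits gave as many as the 1438 genes at 2 weeks (highest other 3141). For the 1343 genes at 5 weeks 8 of 35 did (highest other 2686), and for the 1696 between 2 and 5 weeks 4 of 35 (highest other 2853). Of list counts, 29 of 35 splits gave 15 or more at 2 weeks (highest other 31), 7 of 35 gave 23 or more at 5 weeks (highest other 27) and 9 of 35 gave 21 or more between 2 and 5 weeks (highest other 26). The split with 503 genes exchanged control replicate 3 and 2-week replicate 4, which points to a structure of the libraries that the groups do not follow.

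The mean of the neutrophil, monocyte, NK, B and T cell lists was higher at 5 weeks by 0.61 ± 0.22 (log2, SE, 12 libraries). For a lower share of lung tissue cells, the prediction was that interstitial macrophage markers rise like these lists. These lists rose by 0.818 ± 0.17 more than interstitial macrophage markers. Interstitial macrophages lie in the lung tissue and could fall with it, so this difference does not decide the question. Blood retained in the lungs may account for part of the rise. With the red cell list as a covariate the difference was 0.465 ± 0.289 (0.59 ± 0.35 without the 3 libraries that stand apart), too imprecise to decide, so retained blood and a rise of leukocytes in the lung cannot be told apart. Length of treatment, age and diet stay open and untested.

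Glucocorticoid response genes differed between treated and control mice by -0.30 ± 0.09 (log2, SE, 12 libraries). Another time of day at tissue collection could shift the arms of the circadian clock against each other. The clock phase score over 9 genes differed from the controls by 0.06 ± 0.14 at 2 weeks and -0.08 ± 0.14 at 5 weeks, which shows no shift of that kind. The score rises and falls over the day, so different times can share a value, and another collection time is not excluded. Without the 3 libraries that stand apart the difference was -0.253 ± 0.115, too imprecise to say whether those libraries carry part of it. A difference in handling or in stress hormone level between the groups stays open and was not tested.

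Leukocyte, macrophage and smooth muscle lists set 2-week replicate 4 apart from the other 2-week libraries, and no biological explanation was tested. A control sample under this label, or an exchange with control replicate 3, stays open. Of 200 genes chosen between controls and the other 2-week libraries, 69% lay nearer to the control mean. Of 200 genes chosen between controls and the other treated libraries 23.5% did, against 36% to 68.5% (SD 15.7) for controls and 18% to 41.5% for the other treated libraries, each held out in turn. The share lay below every control, but by less than that SD, a margin required only after the result was seen. A test of the glucocorticoid response genes was dropped, because they had been singled out with this library among those where they were lower. A 5-week sample under a 2-week label remains a candidate explanation, since 93.8% of the 386 genes that passed between the other libraries lay nearer to the 5-week mean, above the bound set for it beforehand. That bound was set aside after the libraries labelled as 5 weeks, held out in turn over 200 genes, gave only 55.5% to 79.5%, against 10% to 18% for the other 2-week libraries. In those fits 2-week replicate 4 stayed in the 2-week group, which may have lowered the shares of the 5-week libraries. They are therefore not a like reference for its own share and do not settle whether the bound holds. In this library Angptl4 stood at 22.1 CPM against at least 50.98 CPM at 5 weeks, and aryl hydrocarbon receptor targets at 5.49 against at most 5.07. Both also lay outside the controls, at 35.6 to 74.4 CPM and 4.87 to 5.20. Its own Zbtb16, Map3k6, Fkbp5, Slc26a4 and Nr4a3, at 10.5, 22.05, 21.4, 1.79 and 7.80 CPM, lay below every control (lowest 77.3, 67.5, 48.9, 3.28 and 19.3 CPM), as did its glucocorticoid list mean (6.12 against at least 6.57). Control replicate 3 had Zbtb16 at 89.3 CPM, against 16.7 to 28.3 CPM in the other 2-week libraries. In 2-week replicate 4, Zbtb16, Map3k6 and Fkbp5 also lay below every 5-week library (lowest 34.3, 28.5 and 25.7 CPM). So did its glucocorticoid list mean (lowest 6.24), while its Slc26a4 and Nr4a3 lay within the 5-week range. Angptl4, aryl hydrocarbon receptor targets and the levels below every 5-week library go against either label, and the others against a control label or an exchange. All were picked with these libraries in their groups and decide nothing, so a wrong label and an unusual mouse cannot be told apart.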

How the results depend on the processing

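The alternatives without the 3 libraries that stand apart, the exact permutation of list means, and the left-out libraries for lists and for the correlation of changes were chosen after seeing the data. Gene counts past the threshold were 0 under both pseudocounts, both filters, both other scalings, robust moderation, the fold minimum, fits of only the groups compared and without the 3 libraries. Library weights, which ran from 0.21 for 5-week replicate 3 to 2.56, gave 18 genes at 2 weeks, 0 at 5 weeks, 881 between 2 and 5 weeks and 286 over the 3 groups. The cause was not tested. Leaving out 1 library gave 0 to 24 genes at 2 weeks (24 without 5-week replicate 3, 1 without control replicate 1) and 0 to 1 at 5 weeks (1 without control replicate 1). It gave 0 to 386 between 2 and 5 weeks (386 without 2-week replicate 4) and 0 to 134 over the 3 groups (134 without 2-week replicate 4, 5 without 5-week replicate 3, 2 without control replicate 1). Over all alternatives, genes at an unadjusted p under 0.05 numbered 943 to 2466 (as reported 1438) at 2 weeks, 880 to 1701 (as reported 1343) at 5 weeks, 1075 to 3842 (as reported 1696) between these times and 1065 to 3389 (as reported 1681) over the 3 groups. List counts at 2 weeks, 5 weeks and between them were 0, 0 and 0 with an estimated correlation, 0, 0 and 3 with fry, and 0, 0 and 0 by exact permutation of list means (lowest adjusted p = 0.627, 0.386 and 0.252). The permutation counts are close to fixed by the design, because at the smallest p of 0.0286 a list passes only if most of the 44 lists share it, and 2, 1 and 5 did. The estimated correlations lay between -0.16 and 0.97 over lists, where the preset was 0.01. List counts stayed within 1.5 times with ranks, median-of-ratios scaling, each library left out and without the 3 libraries. Median-of-ratios scaling ended the calls of monocyte markers (adjusted p = 0.0747) and cell cycle genes (adjusted p = 0.0511) at 2 weeks, and ranks that of the IL-1 family at 5 weeks (adjusted p = 0.0607). With 1 library left out the adipocyte mean ran from -1.091 to 0.16 at 2 weeks and from -1.147 to 0.104 at 5 weeks, turning without control replicate 2. Without the 3 libraries it was 0.246 at 2 weeks, where Cidec turned to 0.133. The ribosomal mean at 5 weeks ran from -0.013 (without 5-week replicate 3) to 0.222 and was -0.003 without the 3 libraries. Of 708 fits of a passing list with 1 library left out, 667 kept the call, 38 lost it and 3 turned. Without the 3 libraries 49 of the 59 calls were kept, 8 lost and 2 turned. The correlation of the 2-week and 5-week changes was 0.123 to 0.454 with 1 library left out, and turned to -0.055 with the controls split, since shared controls add to it by construction. Scaling left the median of all genes at or under 0.019 in size in each comparison. Tests on recovered whole counts with edgeR and DESeq2 were not run, because whole reads could not be recovered, and the correlation over genes past the F-test was not run, because none passed. Of 2855 alternatives over the named genes, 1 turned a direction and 66 brought a gene past the threshold. Whole reads were not recovered, so what the depth limits could not be separated from the spread between mice.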

Other observations

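The tie between Il1b and neutrophil markers was tested only after the values were seen.

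Alveolar type 1, type 2 and aerocyte markers passed in none of the 3 comparisons with camera. Against controls, alveolar type 2 cell markers differed by a mean log2 of 0.01 and 0.10 at 2 and 5 weeks (limma camera adjusted p = 0.974 and 0.109). Alveolar type 1 markers differed by 0.13 and 0.11 (adjusted p = 0.0636 and 0.133) and markers of alveolar capillary aerocytes by 0.05 and 0.05 (adjusted p = 0.508 and 0.552). Interferon response genes stood at 0.00 and 0.11, hypoxia and glycolysis genes at 0.02 and -0.08, and cytokine, chemokine and NF-kB target genes at -0.02 and 0.03. Plasma cell markers stood at -0.20 and 0.13, mast cell, basophil and eosinophil markers at -0.18 and 0.01, and mesothelial markers at 0.04 and -0.08. The plasma and mast cell differences depend on control replicate 2. It stood at 5.372 for plasma cells, against 3.829 to 4.149 in the other controls and 4.334 to 4.625 at 5 weeks. For mast cells it stood at 4.356, against 3.35 to 3.574 in the other controls. Fatty acid oxidation genes stood at 0.01 and 0.03, antioxidant genes at 0.05 and 0.01 and histone genes at 0.20 and 0.04. None of these lists passed with camera. Thymus, upper airway and sex-linked lists had 4, 3 and 4 tested genes and were not tested. Cyp1a1, a target of the aryl hydrocarbon receptor named after its values were seen, had a log2 difference of -3.06 ± 0.76 (SE) between 5 and 2 weeks. It passed adjusted over its list alone (limma adjusted p = 0.0118) but not over all genes (limma adjusted p = 0.288).

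A hypothesis drawn from these data is that Il1b in whole lung follows the content of neutrophils. Over the 12 libraries, Il1b correlated with the neutrophil marker list with Pearson's r of 0.96 (permutation p = 1e-05, adjusted 4e-05) and Spearman's rho of 0.972 (permutation p = 1e-05, adjusted 4e-05). The raw p is the smallest that 100000 permutations can give, and r was 0.934 without the 2 libraries farthest from the median. Within groups, on deviations from the group means, r was 0.908 (permutation p = 3e-05, adjusted 0.00012), rho 0.902 (permutation p = 0.00018, adjusted 0.00072) and r 0.854 without the 2 farthest libraries. The family held 4 relations. The within-group permutations shuffled the 12 deviations freely, although deviations in a group constrain each other. Those p-values are therefore too small, and that of monocyte markers is too close to the threshold to count as passing. For monocyte markers within groups r was 0.675 (permutation p = 0.0162, adjusted 0.0324), rho 0.566 (permutation p = 0.0583, adjusted 0.117) and r 0.695 without the 2 farthest libraries. For alveolar macrophage markers r was 0.433 (permutation p = 0.159, adjusted 0.212), rho 0.322 (permutation p = 0.307, adjusted 0.409) and r 0.335 without the 2 farthest libraries. For interstitial macrophage markers r was 0.16 (permutation p = 0.627, adjusted 0.627), rho 0.252 (permutation p = 0.43, adjusted 0.43) and r 0.663 without the 2 farthest libraries. The values are consistent with neutrophils as a source of Il1b transcript, or with monocytes or blood content that vary together with them, which whole-lung RNA does not separate.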
